A study of Rattus norvegicus with 6 samples.

How the data were processed

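Gene expression was measured in the liver of male Sprague-Dawley rats, 3 given corn oil and 3 given o-anthranilic acid at 1000 mg/kg/day, with 1 array per rat. The rats were 5 weeks old when purchased. The labels disagree on the length of dosing: the treatment protocol gives 9 weeks and the series design gives measurement at 28 days, so the duration behind every value below is open. Replicates are different animals per the labels.

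Each array was a single-colour Agilent array (Cy3) with 61657 non-control probes, of which 796 carry custom names beginning with C_CA. Per the file headers, the spot intensities were extracted with Agilent Feature Extraction 10.7.1.1, which subtracted the background, removed spatial trends and raised dim spots to a small positive value. The submitters' processing notes name Agilent Feature Extraction 10.7. The deposited intensity files were not normalised between arrays. The authors' deposited table for the whole series holds, for each probe and array, a ratio of that processed signal to a single value per array. This value lay within 0.0355% to 0.126% of the array's 75th percentile, and the medians of the 6 columns ranged from 0.0887 to 0.0976. How the submitters arrived at the scaling is not given in the sources used here, and the table served only as an alternative.

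For the main analysis the processed signal was log2-transformed and the 75th percentile over non-control probes was subtracted on each array. Control spots were left out, as were 14 spots flagged as outliers among 369942 non-control spots. A probe was tested if it was well above background on all 3 arrays of at least 1 group, and had at least 2 unflagged spots in each group, which left 33428 probes. Genes were named by matching the probe's accession, without version, to the RefSeq gene table of the GRCr8 assembly. The file headers name the older rn4 build, so no coordinates are given. Of the 61657 probes, 27460 (44.5%) matched a symbol, and 34197 are unnamed here. The 17250 tested probes with a symbol covered 10257 genes, of which 4979 had more than 1 tested probe. A gene was represented by its tested probe with the highest mean signal.

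Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 4 residual and 2.30 prior degrees of freedom), and p was adjusted over all tested probes by the Benjamini-Hochberg method at a threshold of 0.05. All adjusted p-values for probes and genes are from this limma fit. Differences are anthranilic acid minus corn oil on the log2 scale, with the standard error (SE) of the fit and 3 arrays per group. A probe not well above background on any treated array has only a bound there. Its fold is written as at least the control mean over the higher, on each treated array, of its own signal and the lowest signal among probes well above background.

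The design, the 28 gene lists and the rule for naming genes were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry asks whether the genes of a list move on balance 1 way, and its mixed form whether they change in either direction. The rule named the genes past the threshold with the largest changes. As no gene representative passed, it named the 10 genes with the smallest p in each direction, and the 2 members of every list with the smallest p, all given as values. Other list members are named where a list is described. Some genes that the rule names, or that a list holds, are not reported here.

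The procedure was tested on simulated data over 33425 probes with 200 changed in each of 10 runs. The means were the real ones. The spreads were those that limma had shrunk towards a common value, which vary less between probes than the observed spreads. Noise was independent between probes. The recovered shares depend on the number and sizes of the changes put in, so they need not hold for the real data. The fit recovered 2.8% of changes of 0.5 on the log2 scale, 66.4% of changes of 1, 94.4% of changes of 2 and 99.6% of changes of 4, and 5.12% of its calls were false. Camera called 20 of 20 lists of 15 genes shifted by 0.5, and 1 of 380 unshifted lists, on genes simulated as independent of each other.

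Per the file headers, 5 arrays (all 3 corn oil arrays and anthranilic acid replicates 1 and 2) lay on slide 1 and were scanned together, and anthranilic acid replicate 3 lay on slide 2. Slide as a fixed block therefore uses the same comparison as leaving out that array. On slide 1 the corn oil arrays lay in row 1 and the treated arrays in row 2, so that row and treatment cannot be told apart there. Alternatives covered background correction (normexp, offset 50, on the median spot and background signals, because the files hold no mean signal), scaling, the filter on dim probes, slide and replicate number as blocks, the variance model, array weights, the deposited table, the threshold, the choice of probe and leaving out each array in turn. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.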

Results

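Liver RNA from 6 male rats was hybridised to single-colour arrays to ask how repeated dosing with o-anthranilic acid (2-aminobenzoic acid, a breakdown product of tryptophan) changes gene expression. There were 3 rats given corn oil, the vehicle, and 3 rats given anthranilic acid at 1000 mg/kg/day. The dosing time is 9 weeks in 1 label and 28 days in another. Between 53.3% and 58.0% of the 61657 probes were well above background on each array, and the 75th percentile of the signal lay between 489 and 523. No spot was saturated. Across probes, pairs of arrays correlated at r = 0.987 to 0.992 within a group and at r = 0.984 to 0.989 between groups. The first principal component held 33.5% of the variance and placed all 3 treated arrays on one side of all 3 corn oil arrays.

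Livers of treated rats had lower signals for heat shock protein genes as a group (camera adjusted p = 1.39e-05, and adjusted p = 0.182 with an estimated correlation). Adjusted over the list alone, 5 of the 8 measured genes fell, namely Hspa1a, Hspb1, Hsp90aa1, Hsph1 and Hspa8, whereas over all probes 0 of 8 passed by limma, against 5 at unadjusted p under 0.05. A probe each for the growth factor receptor Gfra1 and the cell cycle inhibitor Cdkn1a fell, and a probe for the glutathione transferase Gsta3 rose. Other probes of Gfra1, Cdkn1a and Gsta3 did not pass. The other Gfra1 probe stood at -4.70 (limma adjusted p = 0.0649). The other Cdkn1a probes stood at -0.14 and -2.82, and those of Gsta3 at 0.53 and 0.60, against 2.97 at the called Gsta3 probe. As groups, genes of fatty acid oxidation and of the interferon response were lower by camera, and lymphocyte markers and NRF2 targets were higher. All 4 of these calls were lost with an estimated correlation (adjusted p = 0.534 for each), and that of NRF2 targets also with slide as a block (adjusted p = 0.0542). Of 33428 tested probes, 11 passed the limma test at adjusted p under 0.05, 3 higher and 8 lower in treated livers.

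None of the 11 probes represented its gene, so the count of changed genes was 0 of 10257 by limma, against 1193 genes (11.6%) at unadjusted p under 0.05. Alternative fits gave 8 genes with normexp background correction, 4 with a trended robust variance and 2 with array weights. At adjusted p under 0.1 there were 50 probes, 10 higher and 40 lower, and 5 genes. The signals of the 2 groups did not overlap for 19.8% of genes, where chance gives 10%.

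Among the 11 probes, 4 had a gene symbol. They are named here after their values were seen, because the naming rule covers only gene representatives. Gfra1 encodes the receptor for glial cell line-derived neurotrophic factor. Its probe A_44_P107308 fell from above background on 3 corn oil arrays to not well above background on any treated array, at least 10.8-fold lower (adjusted p = 0.0189). The brighter Gfra1 probe, measured on all 6 arrays, differed by -4.70 (SE 0.47, adjusted p = 0.0649), or 26.0-fold. Cdkn1a probe A_44_P515275 fell at least 3.03-fold (adjusted p = 0.000265), again to signals not well above background. A second Cdkn1a probe, A_44_P914438, differed by -2.82 (SE 0.32, adjusted p = 0.0918), whereas the brightest, A_64_P123895, differed by -0.14 (SE 0.09, adjusted p = 0.571).

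Gsta3, an alpha-class glutathione transferase, rose by 2.97 (SE 0.24, adjusted p = 0.0486) at probe A_64_P035291. Its 2 brighter probes gave 0.53 (SE 0.11) and 0.60 (SE 0.11), with adjusted p of 0.207 and 0.191. Mup4l4, a major urinary protein gene, fell by 2.02 at probe A_64_P142564 (SE 0.16, adjusted p = 0.0486), while its 2 brighter probes gave -0.31 and -0.19. Both genes belong to families with closely similar copies, so the assignment of a signal to 1 copy is uncertain. The shifts of 2 probes of a gene were also compared directly, over the 9238 pairs above background on all 6 arrays (a restriction chosen after seeing the data), and 0 passed by limma, against 690 at unadjusted p under 0.05. Cdkn1a probes A_44_P914438 and A_64_P123895 differed in their shift by -2.68 (SE 0.29, adjusted p = 0.0877), and Mup4l4 probes A_64_P123341 and A_64_P142564 by 1.71 (SE 0.13, adjusted p = 0.0691, or 0.0328 over all 9800 pairs). For Gsta3 the pairs that involve A_64_P035291 had adjusted p of 0.0727 and 0.0735. Without the restriction, 3 of the 9800 pairs passed by limma. They included Cdkn1a probes A_44_P515275 and A_64_P123895 (adjusted p = 7.34e-05), of which A_44_P515275 gives only a bound.

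**Figure D1:**
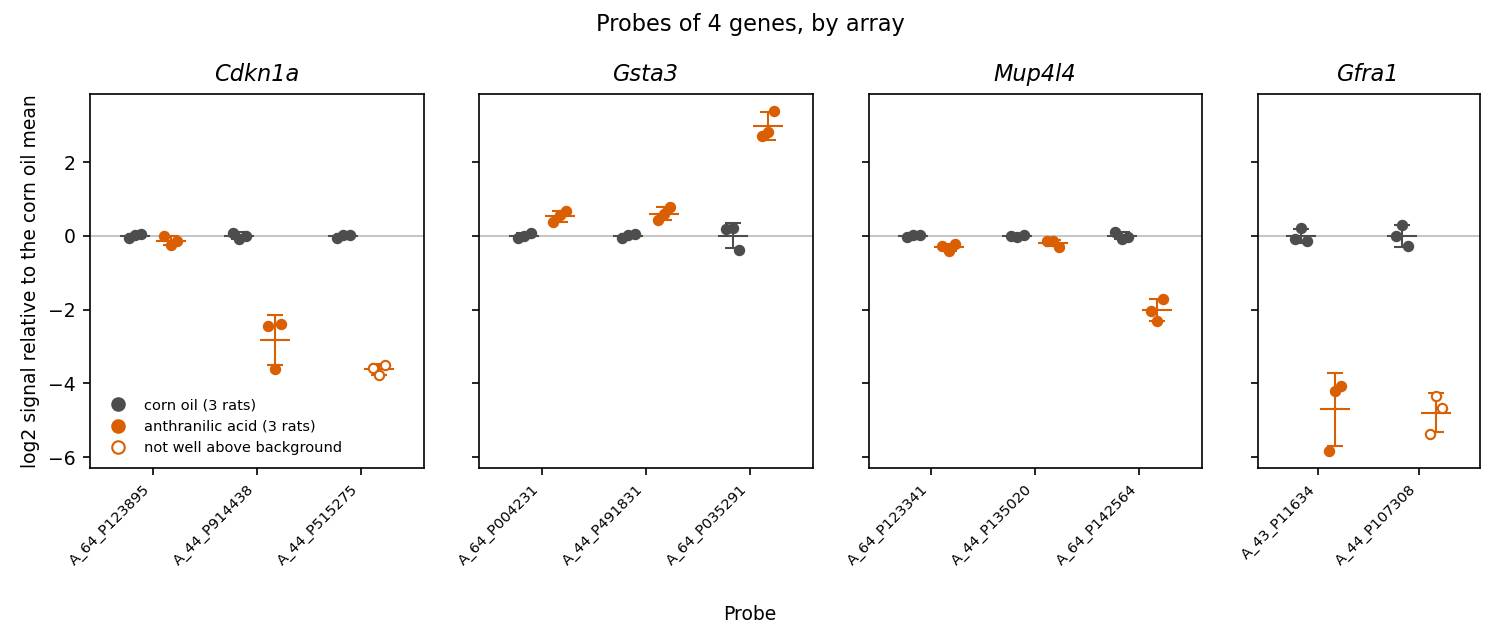
Log2 signal of every tested probe of Cdkn1a, Gsta3, Mup4l4 and Gfra1 on each array (points), relative to the corn oil mean of that probe, with the group mean and SD (bars, n = 3 rats per group). Open points (Gfra1 A_44_P107308 and Cdkn1a A_44_P515275 in treated livers) are not well above background and show only a bound, while the other Gfra1 probe lies at -4.70 and the other Cdkn1a probes at -0.14 and -2.82.

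The other 7 probes have no symbol here. The 2 that rose were A_64_P023008, by 1.53 (adjusted p = 0.0189), and the custom probe C_CA_B0070, by 2.24 (adjusted p = 0.0469). Of the 5 that fell, A_64_P022907 did so at least 5.47-fold (adjusted p = 5.09e-05), and the custom probe C_CA_B0056, above background on all 6 arrays, by 4.66 on the log2 scale (adjusted p = 0.0303). A_44_P434724 fell at least 9.97-fold and A_44_P352071 at least 1.54-fold, both to signals not well above background. The custom probe C_CA_D0008 fell by 1.65 (adjusted p = 0.0486 for each of these). A probe without a symbol may still belong to a gene that a list holds but that counts as not measured here.

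The 10 genes with the smallest p among those higher in treated livers ranged from 0.60 to 1.48, with adjusted p from 0.0604 to 0.131, so none passed. Srpk3, a kinase of splicing factors, was at 1.31 (SE 0.13) and Slc17a3, an organic anion transporter, at 0.94 (SE 0.10, adjusted p = 0.0649). Ptgis, the prostacyclin synthase, was at 1.48 (SE 0.22), Fcer2, the low-affinity IgE receptor of B cells, at 1.21 (SE 0.18), and Akr1d1, the steroid 5-beta-reductase of bile acid synthesis, at 0.79 (SE 0.11). Prkab1, a subunit of AMP-activated kinase, was at 0.81, Cmahp at 0.75, the adhesion molecule Cdh1 at 0.71, the forkhead factor Foxk1 at 0.67 and Chmp4c at 0.60. Among the 10 lower genes the values ran from -4.70 to -0.66, with adjusted p from 0.0649 to 0.120. They held Gfra1 and 3 chaperone genes, Hspa1a, Hsp90aa1 and the DnaJ-family Dnaja4 (-0.88, SE 0.10). The JNK scaffold Mapk8ip1 was at -0.70 (SE 0.08), Mup4 at -0.68, the carbonic anhydrase Car7 at -1.08, Oas1e of the oligoadenylate synthetase family at -0.89 and Sbk1 at -0.66. Rfx5, a regulator of MHC class II genes, was not well above background in any treated liver, at least 2.98-fold lower. All 20 genes had 3 treated arrays on one side of 3 corn oil arrays.

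Of 28 gene lists, camera called 6, 4 lower and 2 higher. With an estimated correlation it called 0, with a smallest adjusted p of 0.182, and fry called 3, with 4 lists under an unadjusted p of 0.05. Other groupings of the 6 arrays gave between 2 and 8 camera calls.

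Heat shock proteins, chaperones of which many are induced by protein damage, were lower as a group, with a median difference of -0.58 over 8 measured genes (camera adjusted p = 1.39e-05). The list had adjusted p = 0.182 with an estimated correlation and adjusted p = 0.00237 by fry. There were 5 of 8 genes that fell when adjusted over the list alone and 3 that did not pass, against 0 of 8 by limma over all probes and 5 at unadjusted p under 0.05. Hspa1a, the inducible Hsp70, was at least 9.90-fold lower and not well above background in any treated liver. Hspb1, a small heat shock protein, fell by 1.99 (SE 0.48), Hsp90aa1 by 0.86 (SE 0.11), Hsph1 by 0.68 (SE 0.14) and Hspa8, the constitutive Hsp70, by 0.49 (SE 0.09). All 6 probes of Hsp90aa1 had differences below 0. The mitochondrial chaperones Hspd1 and Hspe1 stood at -0.06 and 0.01, and Bag3 at -0.37. With slide as a block, which is also the value within slide 1, the list median was -0.56 (camera adjusted p = 3.75e-05).

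**Figure D2:**
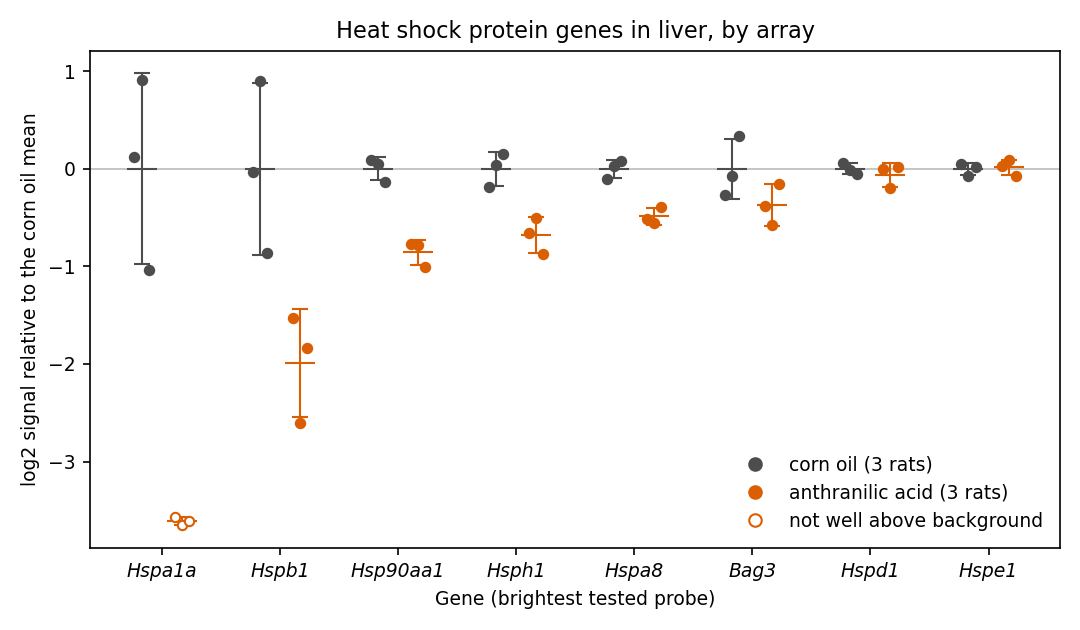
Log2 signal of the 8 measured heat shock protein genes on each array (points), relative to the corn oil mean of each gene, with the group mean and SD (bars, n = 3 rats per group). The 3 treated arrays lie below all corn oil arrays for Hspa1a, Hspb1, Hsp90aa1, Hsph1 and Hspa8, while Hspd1 (-0.06) and Hspe1 (0.01) overlap. Treated signals of Hspa1a (open points) are not well above background and show only a bound.

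PPAR-alpha targets and genes of fatty acid oxidation were lower as a group, with 23 of 26 members below 0 and a median of -0.29 (camera adjusted p = 5.79e-05). The call was lost in the other tests, with adjusted p = 0.534 with an estimated correlation and adjusted p = 0.270 by fry. Adjusted over the list alone, 0 of 26 passed by limma, against 4 at unadjusted p under 0.05. These were Creb3l3 (-0.32), the lipase inhibitor Angptl4 (-0.43), the thioesterase Acot2 (-0.67) and the acyl-CoA dehydrogenase Acadm (-0.26). Cyp4a1, a marker of PPAR-alpha activation, was at 0.04, whereas Cyp4a2, Cyp4a3 and Cyp4a8 were at -0.79, -0.29 and -0.85 (limma adjusted p = 0.426, 0.583 and 0.485). The median was -0.28 with slide as a block, and -0.16 without corn oil replicate 1.

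Interferon response genes had a median of -0.47, with 17 of 21 lower (camera adjusted p = 0.000511), and adjusted p = 0.534 with an estimated correlation and adjusted p = 0.405 by fry. Adjusted over the list alone, 0 of 21 passed by limma, against 5 at unadjusted p under 0.05. Usp18, a deubiquitinating enzyme of the pathway, was at -1.51 (SE 0.44), Oas1a at -1.35 (SE 0.55), Irf7 at -0.87 (SE 0.38) and Gbp2 at -0.33 (SE 0.12). Corn oil replicate 2 had the highest list signal, and without it the median was -0.28. With slide as a block it was -0.48 (camera adjusted p = 0.0131).

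Lymphocyte markers were higher as a group, 9 of 10 members, with a median of 0.35 (camera adjusted p = 0.00105), and adjusted p = 0.534 with an estimated correlation and adjusted p = 0.270 by fry. Adjusted over the list alone, 2 of the 10 rose, among them the B cell gene Cd79b (1.11, SE 0.22), and the other 8 did not pass, against 4 at unadjusted p under 0.05. Over all probes, 0 of the 10 passed by limma. The T cell genes Cd3g and Cd8a were at 0.52 and 0.34, and Klrd1 of natural killer cells at -0.01. The median was 0.41 with slide as a block and 0.18 without anthranilic acid replicate 1. Erythroid markers, genes of red blood cells, had a median of 0.39 with all 5 measured genes above 0 (camera adjusted p = 0.157).

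NRF2 targets, the antioxidant and conjugation genes, were higher in 14 of 17 members, with a median of 0.25 (camera adjusted p = 0.0194), and adjusted p = 0.534 with an estimated correlation and adjusted p = 0.270 by fry. Of these, 5 rose and 1 fell when adjusted over the list alone, whereas 0 of 17 passed by limma over all probes, against 5 higher and 1 lower at unadjusted p under 0.05. The quinone reductase Nqo1 was higher by 1.59 (SE 0.47) and the aldo-keto reductase Akr7a3 was 2.82-fold higher (SE 0.37 on the log2 scale). Corn oil replicate 3 had a lower Nqo1 signal (-0.57) than corn oil replicates 1 and 2 (1.25 and 1.07), which widens the Nqo1 difference. The export pump Abcc3 rose by 0.73 (SE 0.18), Gsta3 by 0.53 and Ugdh by 0.37, while Srxn1, the sulfiredoxin, fell by 0.51 (SE 0.15). Hmox1 and Gsr were at -0.07 and 0.01. The call ended with slide as a block (median 0.28, adjusted p = 0.0542), without corn oil replicate 3 (median 0.16, adjusted p = 0.0761) and without the filter on dim probes (adjusted p = 0.0579).

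Only 4 markers of pancreas, fat and muscle were measured, all lower, with a median of -0.30 (camera adjusted p = 0.0371), adjusted p = 0.534 with an estimated correlation and adjusted p = 0.0450 by fry. They included the myoglobin gene Mb (-0.32) and the chymotrypsinogen gene Ctrb1 (-0.28). The call ended with slide as a block (median -0.30, adjusted p = 0.0895) and under 6 further alternatives.

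**Figure D3:**
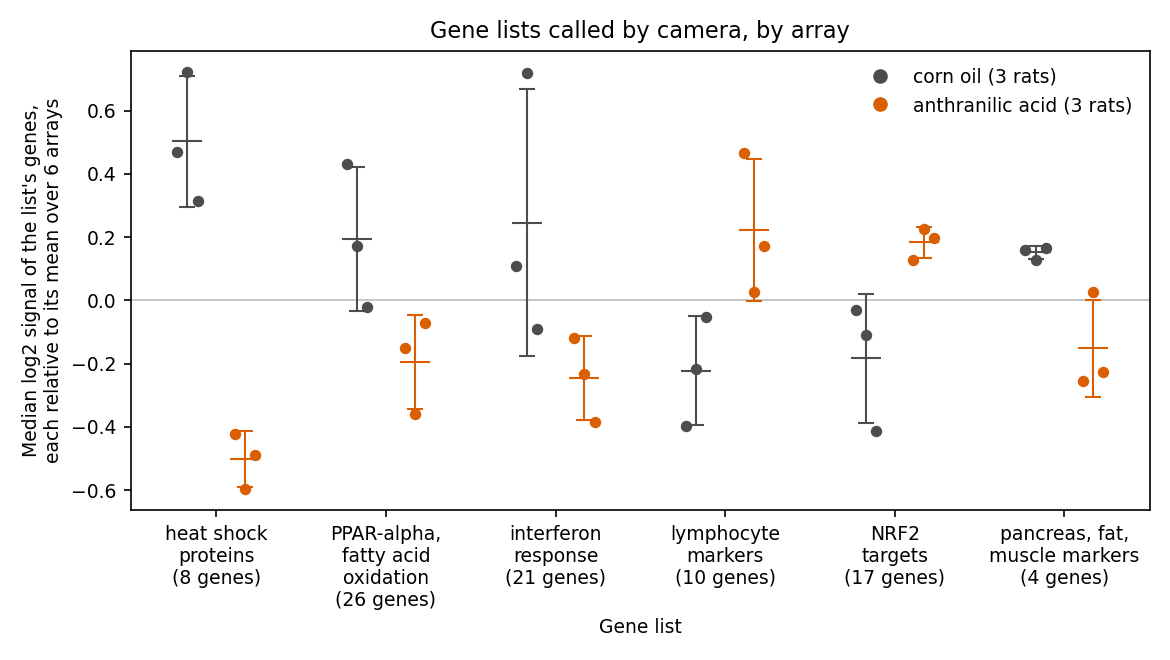
Mean log2 signal over the genes of each list that camera called, on each array (points). Each gene was set relative to its mean over the 6 arrays, and bars show the group mean and SD (n = 3 rats per group). The axis label reads median, but the points are means over genes. The heat shock means include Hspa1a, whose treated signals are not well above background. Heat shock proteins separate the groups most widely, from 0.32 to 0.72 in corn oil and from -0.60 to -0.42 in treated livers, and the interferon list of corn oil replicate 2 (0.72) stands apart from the other corn oil arrays.

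Of the other 22 lists, hepatocyte markers had a median of -0.06, with all 10 members lower (camera adjusted p = 0.0710, fry adjusted p = 0.0361). Apoa1, the main protein of high-density lipoprotein, was at -0.57 (SE 0.15) and transferrin (Tf) at -0.12. Among markers of other liver cells, Kupffer cell and macrophage markers had a median of -0.19 (camera adjusted p = 0.269), neutrophil markers 0.52 over 3 genes (0.157), endothelial markers -0.08 (0.322), cholangiocyte markers 0.31 (0.299) and stellate cell and matrix genes -0.04 (0.999). Lyz2 of macrophages rose by 0.53 (SE 0.10) adjusted over the list alone, against Cd163 at -0.40. Neutrophil S100a8 and S100a9 were at 0.60 and 0.52, endothelial Lyve1 and Eng at -0.34 and 0.21, cholangiocyte Epcam and Krt19 at -0.53 and 0.60, and Vim and Col1a1 of the stellate list at 0.25 and 0.24. The stellate list had a mean of 0.02, opposite in sign to its median. It was measured for 12 of its 14 genes, and Lox, for which no probe was matched, is not among them. In the erythroid list, Alas2 was at 0.56 and Hbb-b1 at 0.39.

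Lists of drug-metabolising and stress genes were also not called. CAR and PXR targets had a median of -0.33 (camera adjusted p = 0.0856), with the glucuronosyltransferase Ugt2b1 at 0.97 (SE 0.22) and Gstm3 at -1.88 (SE 0.60), or -1.27 without anthranilic acid replicate 2. Only 4 AhR targets were measured, with a median of 0.07 (adjusted p = 0.299), and Cyp1a2 was at -0.07 beside Nqo1 and Aldh3a1 (0.18). For conjugation of aromatic acids and amines, the routes by which compounds such as benzoic acids are cleared, the median was -0.02 over 13 genes (adjusted p = 0.877) and the mean -0.18, although camera's direction was higher. Acsm5 was at -1.96 (SE 1.30), but at -3.55 without anthranilic acid replicate 3, and at -0.999 and -1.33 without replicates 1 and 2 of that group, and its other probes gave -0.39 and 0.85. Acsm1 was at 0.12 and the glycine N-acyltransferase Glyat at 0.07. The p53 and DNA damage list had a median of -0.04 (adjusted p = 0.180), with Tp53inp1 at -0.72 (SE 0.16), Abcb1b at -0.58 (SE 0.15) and Mdm2 at -0.24. Unfolded protein and amino acid stress genes had a median of -0.01 (adjusted p = 0.868), with the asparagine synthetase Asns at 1.18 (SE 0.40) and Ern1, above background on 1 of 3 treated arrays, at -0.46. Cell cycle genes also had a median of -0.01 (adjusted p = 0.861), with Tyms at -0.23 and Birc5 at 0.21.

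In tryptophan, kynurenine and NAD metabolism, the pathway in which anthranilic acid arises, the median was 0.06 over 16 genes (camera adjusted p = 0.335). Adjusted over the list alone, the kynurenine monooxygenase Kmo rose by 0.48 (SE 0.11) and Qprt, which makes nicotinic acid mononucleotide from quinolinic acid, fell by 0.39 (SE 0.09). The mixed form of fry, which asks for changes in either direction, gave this list an adjusted p of 0.00232. It was under 0.05 for 11 of the 28 lists, among them NRF2 targets and the p53 list (0.00287 each), the urea cycle list (0.00478) and bile acid synthesis (0.0130). Kynu, whose enzyme releases anthranilic acid from kynurenine, was at -0.03, and Tdo2 at 0.42. The urea cycle and amino acid list had a median of 0.09 and a mean of -0.05 (camera adjusted p = 0.499). The ornithine transcarbamylase Otc rose by 0.56 (SE 0.09) adjusted over the list alone, and Got1 stood at -0.89 (SE 0.26).

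Fatty acid synthesis genes had a median of 0.26 (camera adjusted p = 0.0856), with the stearoyl-CoA desaturase Scd at 3.44 (SE 0.82), a 10.9-fold difference with an adjusted p of 0.257, and Gpam at 0.23. The Scd difference was 19.7-fold without corn oil replicate 3 and 6.87-fold without corn oil replicate 2. Cholesterol synthesis had a median of 0.26 (adjusted p = 0.180), with Insig1 at -0.72 and Stard4 at 0.48. In bile acid synthesis and transport the median was 0.04 (adjusted p = 0.299), Akr1d1 rose when adjusted over the list alone, and Slc10a1, the bile acid uptake transporter, was at 0.30. Glucose metabolism had a median of -0.13 (adjusted p = 0.322). Adjusted over the list alone, the pyruvate kinase Pklr rose by 0.59 (SE 0.12) and the gluconeogenic Pck1 fell by 0.64 (SE 0.16). Circadian clock genes had a median of 0.13 (adjusted p = 0.299), with Nr1d1 at 0.60 and Tef at 0.37. Sex-biased and growth hormone-responsive genes had a median of 0.10 (adjusted p = 0.410), with Cyp2c12 at -1.32 and Hsd17b2 at 0.65. The acute phase response had a median of 0.06 (adjusted p = 0.548). Adjusted over that list alone, the interleukin-1 receptor antagonist Il1rn fell by 0.48 (SE 0.10), and Orm1 was at 0.64.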

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

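The number of changed probes, 11, depended on the processing, and the cause was not tested except where the setting itself gives it. It was 50 with normexp background correction, 21 with median scaling, 45 with a trended robust variance, 29 with array weights and 50 at adjusted p under 0.1. It was 2 without the filter on dim probes (61656 tested), 2 when probes had to be above background on all 6 arrays, and 6 with slide as a fixed block, all lower. Quantile normalisation, the deposited table, a fold of at least 2 and raising dim signals to the lowest signal above background (chosen after seeing the data) each gave 11, and slide as a random block gave 9. Leaving out 1 array gave 2 to 8 probes, with fewer arrays to test: 2, 3 and 5 without corn oil replicates 1, 2 and 3, and 8, 7 and 6 without anthranilic acid replicates 1, 2 and 3. Changed genes numbered 0 in the limma fit, against 1193 at unadjusted p under 0.05, and 8 with normexp, 2 with median scaling, 1 with slide as a fixed block, 4 with a trended robust variance, 2 with array weights, and 0 to 2 when 1 array was left out (2 without anthranilic acid replicate 1, and 1 each without replicate 3 of that group or corn oil replicate 2 or 3).

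Gene lists called numbered 6, against 0 with an estimated correlation, 3 with fry, and 5 to 9 when 1 array was left out. The lists for heat shock proteins, PPAR-alpha targets, interferon response and lymphocyte markers passed under all 18 settings of the camera test other than its correlation. NRF2 targets passed under 14 and pancreas, fat and muscle markers under 11. The heat shock median ranged from -0.66 to -0.49. No called probe, called list or gene given by the naming rule reversed under the alternatives run for it. Of 122 named genes and probes that were not called, 13 changed sign, and the cause was not tested. Apart from Cd37 (-0.86), their differences lay between -0.10 and 0.07. With 1 array left out, Cd37 ranged from -1.57 to 0.18, Cd22 ranged from -0.34 to 0.19, Cyp1a2 from -0.31 to 0.12, Cyp4a1 from -0.074 to 0.15, Fos from -0.020 to 0.10, Glyat from -0.045 to 0.14, Gsr from -0.071 to 0.081, Hmox1 from -0.36 to 0.20, Hspd1 from -0.10 to 0.0098, Hspe1 from -0.021 to 0.058, Klrd1 from -0.24 to 0.27, Kynu from -0.20 to 0.14 and St13 from -0.018 to 0.089. With slide as a fixed block, Cyp1a2 was at 0.12, Fos at -0.020, Gsr at -0.071, Hmox1 at 0.0041, Klrd1 at 0.14 and St13 at -0.018. Quantile normalisation gave Cyp4a1 -0.016, Hspe1 -0.053, Klrd1 0.043 and St13 -0.043, normexp Hspe1 -0.015 and Klrd1 0.068, median scaling Klrd1 0.046 and Kynu 0.020, array weights Gsr -0.024 and Klrd1 0.11, and slide as a random block Klrd1 0.010. For the called probes, 48 of 66 values with 1 array left out were no longer past the threshold.

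Both groups carry replicate numbers 1 to 3. Arrays with the same number did not deviate together (r = 0.07, -0.05 and -0.04 across probes). Pairs with different numbers ranged from r = -0.13 to 0.16. The check gave no sign of pairing, but so few arrays cannot exclude it. With replicate number as a block, 2 probes, 0 genes and 8 lists were called. Signal over background limits the Hspa1a, Rfx5, Gfra1 and Cdkn1a folds that are given as bounds.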

Other observations

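The tests of slide, of blood and of the array splits for probes and genes were chosen after the results they bear on had been seen. In addition, the requirement that a 95% interval over arrays lie wholly past a stated bound before an explanation was set aside was added after the values were known. That interval is of the shift over arrays, the difference between the groups in each array's median over the genes, which is not the median of the genes' differences. Without it, the handling and B cell explanations weighed here would each have met the bound written beforehand for setting them aside. For the transporter families, which met their bound of 0.05 but not by that interval, the comparison with the size of the change to be explained was chosen later still.

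A wider set of chaperone genes outside the heat shock list was lower in treated livers, 12 of 15 genes, with a median of -0.28 (fry p = 0.00045, camera p = 1.38e-05 and p = 0.00971 with an estimated correlation). The largest differences were in Hsp90ab1 (-0.56, SE 0.11), P4ha1 (-0.49, SE 0.18), Chordc1 (-0.44, SE 0.13) and Cryab (-0.39, SE 0.14). P4ha1, a collagen prolyl hydroxylase subunit, was in the set but is not itself a chaperone. Hspa4 and St13 stood at 0.17 and 0.03, and 0 of 15 passed by limma over all probes (smallest adjusted p = 0.212), against 9 at unadjusted p under 0.05. Of the B cell genes outside the lymphocyte list, 9 were measured. As a set they did not pass in 1 direction (unadjusted fry p = 0.0875, camera p = 0.0769 and p = 0.140 with an estimated correlation). The mixed form of fry, for changes in either direction, gave an unadjusted p of 0.00147. None of them passed by limma (smallest adjusted p = 0.189), against 3 higher and 1 lower at unadjusted p under 0.05. Pou2af1 was at 0.87 (SE 0.19), Vpreb3, above background on 2 of 3 corn oil arrays, at 0.78 (SE 0.32) and Spib at 0.74 (SE 0.14), whereas Cd37 was at -0.86 (SE 0.87, and 0.18 without corn oil replicate 2), Pax5 at -0.32 (SE 0.11) and Cd22 at -0.10.

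The lower heat shock genes may reflect lower expression of chaperones as a class in treated livers, or higher expression in the corn oil rats. The median of -0.28 in the wider set met the prediction for a class-wide difference, which the set could have failed. Not all chaperone genes shared the difference. The mitochondrial Hspd1 and Hspe1 stood at -0.06 and 0.01. The unfolded protein list, which holds the chaperone genes Hspa5, Hsp90b1 and Calr, had a median of -0.01 (camera adjusted p = 0.868). A class-wide reading therefore covers only part of the chaperones. The wider set was measured in the same livers, so it is not independent support and cannot part these readings. Slide and scan were argued against, since the heat shock list median within slide 1 was -0.56 (shift over arrays -0.56, interval -0.75 to -0.37). Stress or handling of the corn oil rats shortly before sampling stays open, since immediate early genes had a median of -0.14 but a shift over arrays of -0.17 with an interval from -0.77 to 0.43, with Dusp1 at -1.18 (SE 0.51) and Fos at 0.06. Row on the slide also stays open, because it parted the groups within slide 1. The treated array that lay in row 1, as the corn oil arrays did, was a single array on slide 2. Its mean over the list's genes was -0.49, against 0.32 to 0.72 in corn oil.

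The higher B cell marker Cd79b could come from more B cells in the sampled tissue, from more blood, or from a change in expression. The median of the further B cell genes was 0.17, and their shift over arrays 0.23 with an interval of -0.04 to 0.51, which neither bears out nor excludes more B cells. More blood also stays open. Cd79b (1.11) was higher by 0.79 more than the mean of the haemoglobin genes Hbb (0.25) and Hbb-b1 (0.39), which blood would raise at least as much, but the interval of that difference, -0.08 to 1.65, includes 0.

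Slc17a3 (0.94), Abcc3 (0.73) and both probes of Abcg2 (1.69 and 1.81, adjusted p = 0.143 and 0.115, named after their values were seen) encode transporters of organic anions. A shift of these families as a group could underlie this only if the other members moved by about as much. In the Slc22a, Slco, Abcc, Abcg and Slc17a families, the 37 tested genes other than Abcg2 that neither the naming rule nor a gene list held had a median of -0.00195 (SD 0.30, shift over arrays 0.0010 with an interval of -0.08 to 0.08), and all 43 tested members together -0.0012 (SD 0.42, shift 0.02 with an interval of -0.06 to 0.09). Both lie below 0.73, the smallest of the changes, by more than the SD, which argues only against a shift of that size. The 3 genes were picked for their high values, which made a lower median in the other members likely beforehand. What sets the 3 genes apart was not tested. Among the 37, Slc17a1 was at 0.66 (SE 0.16), Abcc8 at 0.85 (SE 0.17) and Slc22a12 at -0.62 (SE 0.20), none of which passed by limma (adjusted p = 0.257, 0.203 and 0.350).

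The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 11 probes, and the highest of the other splits gave 1, so 1 of the 10 splits gave as many. For genes the real count was 0 by limma, against 1193 at unadjusted p under 0.05, and the highest other split gave 1. All 10 splits gave at least 0, which a real count of 0 makes certain, so the comparison cannot decide anything for genes. For gene lists, 4 of the 10 splits gave at least the real count of 6, and the highest other split gave 8. That split set corn oil replicates 1 and 2 with anthranilic acid replicate 3. At unadjusted p under 0.05 the real split gave 4093 probes and the highest other 2226. The median of the heat shock list had a size of 0.58 in the real split and at most 0.29 in the others.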
